A study of Mus musculus with 4 samples.

How the data were processed

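Naive CD8+ T cells were sorted from mouse spleen, cultured for 72 h with the cytokines IL-7 and IL-15, lysed and digested with DNase I, an enzyme that cuts accessible chromatin. The released DNA was sequenced on an Illumina instrument (DNase-seq), per the labels' protocols. There were 4 libraries, 2 from wild-type cells (WT) and 2 from cells lacking the transcription factors Tcf1 and Lef1 (double knockout, DKO). Genotype and replicate number were taken from the sample titles. The labels do not say whether replicates came from separate animals, so the spread between libraries may be technical.

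Each library had its own deposited peak list, so peaks were called per library and not on pooled reads. Bowtie2 2.2.5, FastQC, MACS2 2.1.1 and the mouse build mm9 are named in the submitters' processing notes. Their settings, the use of a control library and the handling of duplicate reads are not given in the sources used here. Every peak lay within the mm9 chromosome lengths. For each peak the authors deposited the fold enrichment, a ratio of the pileup at the summit to the local background. They also deposited the −log10 p and the −log10 q of the peak, and a score that is 10 times the −log10 q. The deposited start, end and summit positions count from 0 and were converted to positions counted from 1. The smallest fold enrichment in each deposited list lay just above 4 and the smallest −log10 p just above 5. The running peak numbers in the names had gaps of 871 to 1530 per list, so peaks had been removed after calling. A fold, p or q is the authors' own value for that peak and was used here to describe, rank or filter peaks within a list.

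Read totals are not given in the lists. MACS2's fold is the pileup plus 1 over the background plus 1, and its p is the Poisson chance of more than that pileup. The pileup and background that give both values were solved for every peak with a −log10 p under 250. The solved pileup was a whole number within 0.02 for 100% of these peaks in each library. On 5000 simulated peaks the solution recovered 100% of the pileups. Where no control library sets it, the lowest background in a library is proportional to its reads times the fragment length used by the caller. It was taken as a sign of depth. It carries no error of its own.

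The peaks of the 4 lists were merged into union regions wherever they overlapped by at least 1 bp. A region was called WT-only when both WT lists and neither DKO list had a peak in it, and DKO-only in the opposite case. On simulated lists, with planted regions far apart and no call missing, 1000 of 1000 regions of each kind were recovered. This checks the counting only, not the effect of missed calls or crowded peaks. Absence of a peak means that the site did not pass the listing thresholds, not that it was closed. Because lists of different length give unequal counts, the counts were repeated with the 11073 peaks of highest −log10 p in each library, the length of the shortest list. The 4 libraries can be split into 2 and 2 in 3 ways, and the counts for the other splits are given beside those for genotype. With 2 libraries per genotype the smallest two-sided exact permutation p is 0.33, so a permutation test of the libraries cannot pass 0.05. Overlap between libraries was measured as the share of peaks overlapping by at least 1 bp and as the Jaccard index, shared bases over all covered bases. Windows of 100 kb on a fixed grid with at least 3 regions of a class were compared with 10000 shuffles of the class over the union regions, one-sided, a permutation test; the central range of the shuffles runs from their 2.5th to their 97.5th percentile. Shares per chromosome were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 42 comparisons. These p-values treat regions as units; regions are not replicates. The regions named are, by rule, the 10 per genotype with the highest value of the lower fold of the 2 libraries, and the 5 windows per genotype with the most regions. For WT, 3 further windows tied with the last of these are named too, added after their values were seen.

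Alternatives covered −log10 q minimums of 5 and 10, equal list lengths, ranking by fold, overlap of a larger part of the peak, merging within 500 bp, windows of 50 kb and leaving out each library. These choices, the union, the classes and the naming rule were fixed before the data were examined. The tests per chromosome, the removal of chromosomes X, Y and M, the fold minimum of 8, the cluster test on other pairs of libraries, the background at X peaks, the search of the full lists for regions classed at equal length and the leave-one-out values for peak number, overlap and clusters were added afterwards. Planned tests of gene lists, promoters, the targeted genes Tcf7 and Lef1, cell type markers and motifs needed a genome and annotation of mm9, which were not used here. Regions are therefore given by mm9 position without a gene. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.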

Results

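DNase I accessibility was mapped in mouse CD8+ T cells held for 72 h in IL-7 and IL-15, cytokines that sustain T cells without antigen. The comparison was between 2 wild-type libraries and 2 libraries from cells in which Cre recombinase had removed Tcf1 and Lef1, related DNA-binding proteins of the T lineage. It asks which accessible sites differ when these factors are absent. The WT lists held 17521 and 11073 peaks and the DKO lists 34788 and 21353 peaks, for replicates 1 and 2. These peaks merged into 38986 union regions, of which 8068 were called in all 4 libraries.

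More sites were called accessible in the DKO cells. The DKO lists held 28071 ± 9500 peaks and the WT lists 14297 ± 4559 (SD, n = 2 each), a ratio of 1.96. They covered 5339 ± 1945 kb and 2788 ± 875 kb of mm9 (SD, n = 2 each). Both DKO lists were longer than both WT lists, by 0.97 on the log2 scale on average. The exact two-sided permutation p was 0.33, the smallest this test allows at 2 against 2. Leaving out WT replicate 1 or DKO replicate 2 raised this log2 difference to 1.30 or 1.32. Leaving out WT replicate 2 or DKO replicate 1 lowered it to 0.64 or 0.62. The background level, which grows with read depth, ran the other way. The lowest background was 1.50 and 1.47 fragments per position in WT replicates 1 and 2, and 1.23 and 1.15 in DKO replicates 1 and 2. The narrowest peak was 93 and 97 bp in the WT lists and 85 and 86 bp in the DKO lists. The median fold enrichment within each list was 6.43 and 6.13 for WT and 8.50 and 7.24 for DKO.

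**Figure D1:**
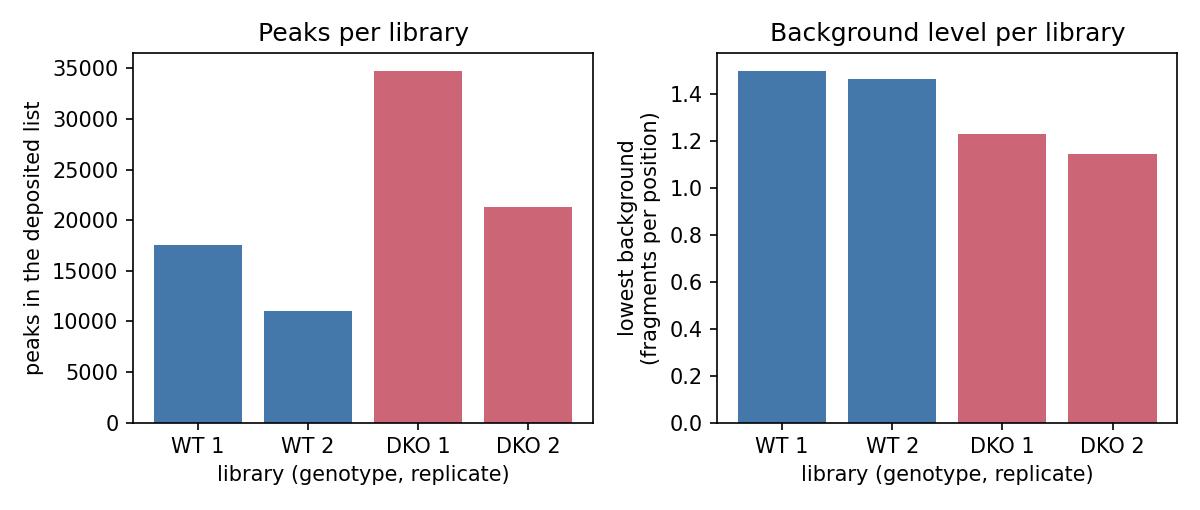
Left, the number of peaks in each deposited list; right, the lowest background in fragments per position. Each bar is 1 library, blue for WT and red for DKO, with no error bar. Both DKO libraries, with 34788 and 21353 peaks, stand above both WT libraries on the left and below them on the right.

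Most sites of the WT cells were also called in the DKO cells. Of the peaks of WT replicate 1, 87.7% overlapped a peak of DKO replicate 1 and 73.6% one of DKO replicate 2. For WT replicate 2 these shares were 91.5% and 82.2%. The reverse shares were lower, since the DKO lists were longer. Of the DKO replicate 1 peaks, 44.1% overlapped WT replicate 1 and 29.1% overlapped WT replicate 2. With lists of equal length, DKO replicates 1 and 2 shared the most bases, with a Jaccard index of 0.53. The WT replicates reached 0.42, below the 0.45 and 0.46 between WT replicate 1 and the DKO replicates. WT replicate 2 reached 0.38 and 0.40 with the DKO replicates. Library similarity at equal length therefore did not follow genotype for WT replicate 1. WT replicate 2 kept its whole list, down to a −log10 p of 5.4, while the other lists were cut at 10.8 or above. Whether this lowered the values of WT replicate 2 was not tested.

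DKO-only regions numbered 5593, or 14.3% of all union regions. Within the DKO replicate 1 list their median fold enrichment was 8.16, against 13.2 for the regions called in all 4 libraries. Within the DKO replicate 2 list these medians were 6.06 and 9.59. In 927 of them (16.6%) both DKO libraries had a fold enrichment of at least 8. For the regions called in all 4 libraries, the medians were lower in WT replicates 1 and 2, at 7.51 and 6.61. A DKO fold of 8 therefore does not mean that a WT list would have held the site. The strongest DKO-only region was one of 320 bp on chromosome 17, 36621604 to 36621923, with folds of 45.6 and 45.0 in DKO replicates 1 and 2. It was followed by X 120325196 to 120325361, with 50.1 and 33.1, and by chromosome 13, 4560483 to 4560762, with 38.2 and 32.3. A pair of neighbouring regions on chromosome 18 was also among the 10 strongest. The region at 7323083 to 7323235 had folds of 41.3 and 31.6, and that at 7320124 to 7320445 had 19.2 and 29.7. On chromosome 14, 54173594 to 54173775 had folds of 26.1 and 29.6. On chromosome 6, 41080288 to 41080562 had folds of 23.5 and 26.7. Chromosome X also held 120777862 to 120778001 with 26.8 and 23.5, and 120337871 to 120338029 with 20.2 and 22.4. All the X regions named here lie in a stretch, 120100001 to 121400000, in which no WT library had a call. That stretch is described below, and reads from Y placed on it stay open. The remaining region of the 10 lay on chromosome 9, 13422613 to 13422879, with 22.7 and 19.8. The count of DKO-only regions rose to 10097 without WT replicate 1 and to 17922 without DKO replicate 2. Leaving out a library can only raise such a count, since a region then has fewer lists to be called in or absent from.

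WT-only regions were fewer. They numbered 246, or 0.63% of the union regions, and 7 of them had a fold of at least 8 in both WT libraries. Their median folds were 5.63 and 5.27 in WT replicates 1 and 2, against 7.51 and 6.61 for the regions called in all 4. Folds ran lower in the WT lists, so the count of 7 is not set against the DKO-only count at that fold. Over the full lists, 2 of the 4 mixed pairs of libraries gave larger counts than the WT pair. Both replicates 1 alone shared 2057 regions, and WT replicate 2 with DKO replicate 1 shared 529. Both replicates 2 alone shared 49, and WT replicate 1 with DKO replicate 2 shared 183. The strongest WT-only region lay on chromosome 7, 134772289 to 134772558, with folds of 11.9 and 10.1. Chromosome 9 held 31078840 to 31079134 with 9.35 and 10.6, and 118105897 to 118106098 with 8.35 and 10.4. On chromosome 11, 105306375 to 105306480 had 9.82 and 8.88. On chromosome 19, 45870843 to 45871064 had 10.2 and 8.60. The widest of the 10, 539 bp on chromosome 10 at 19041426 to 19041964, had 10.7 and 8.38. On chromosome 6, 99436208 to 99436518 had 9.27 and 8.10, and on chromosome 4, 125889175 to 125889386 had 7.92 and 8.77. The remaining regions were chromosome 2, 126746216 to 126746468, with 13.1 and 7.66, and chromosome 17, 57306634 to 57306824, with 9.17 and 7.63. The count of WT-only regions rose to 827 without WT replicate 1, to 1913 without WT replicate 2 and to 812 without DKO replicate 1. Here too the direction was fixed in advance.

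With all lists held to 11073 peaks, the imbalance between the genotypes mostly went. There were then 1057 DKO-only and 847 WT-only regions among 18389 union regions, a ratio of 1.25 against 22.7 over the full lists. Of the 847 WT-only regions, 736 had a DKO peak in the full lists that the cut to equal length removed, and of the 1057 DKO-only regions, 239 had such a WT peak. The cut removed peaks from both DKO lists but from WT replicate 1 only, since WT replicate 2 was the shortest list. These counts therefore depend on the cut and do not compare the genotypes. Both genotype counts were higher than those of every other pair of libraries at this length, which over the full lists did not hold for WT. The next was the pair of WT and DKO replicates 1, with 592 regions called in both and in neither replicate 2. The genotype split gave 1904 regions in all, against 979 for the split by replicate number and 778 for the crossed split. With 3 splits, no such comparison can reach 0.05. Leaving out any 1 of the 4 libraries, which can only raise these counts, gave between 1689 and 2342 DKO-only and between 1302 and 3253 WT-only regions.

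**Figure D2:**
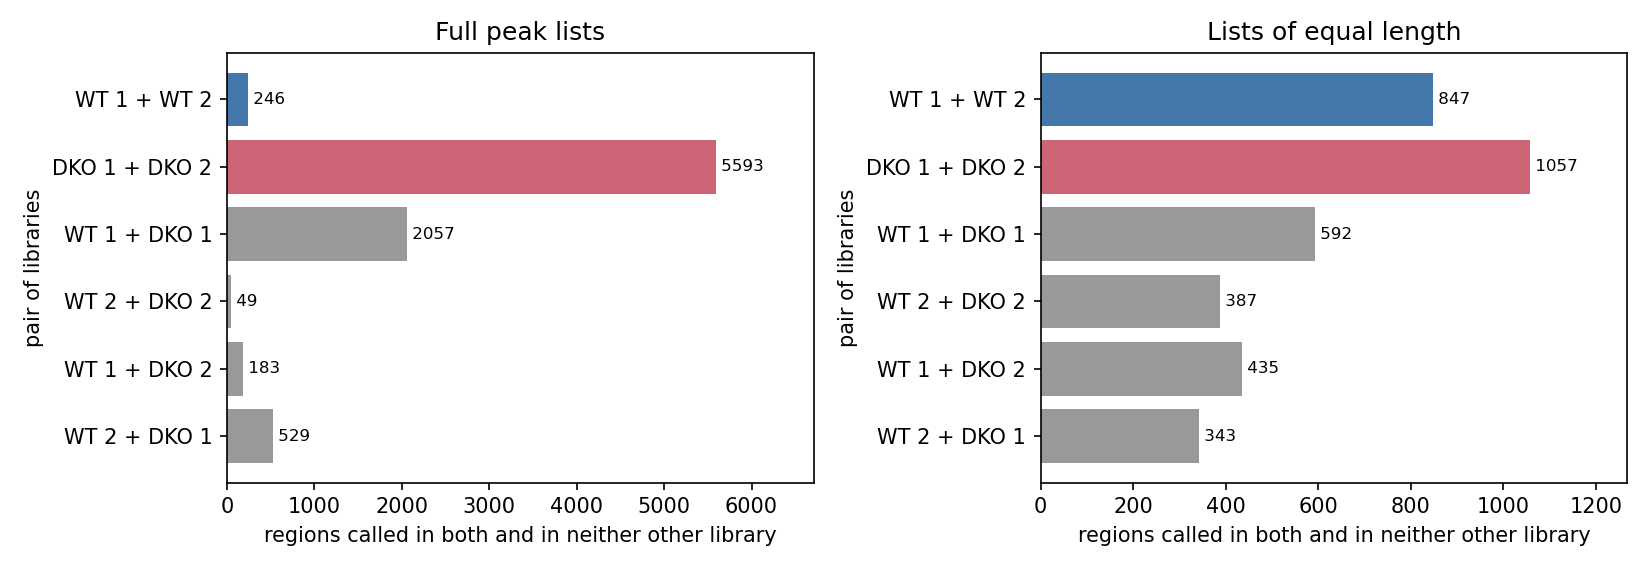
Regions called in both libraries of a pair and in neither of the other 2, for the full lists (left) and for lists of equal length (right); each bar is a count, with WT in blue, DKO in red and mixed pairs in grey. At equal length the genotype pairs, 847 and 1057, exceed the mixed pairs, whose highest is 592.

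Chromosome Y separated the genotypes by calls. No peak of either WT library lay on chromosome Y, while DKO replicates 1 and 2 had 55 and 57 peaks there. Of 68 union regions on Y, 39 were called in both DKO libraries, between 346915 and 2901932, and 52 lay in the stretch from 2700001 to 2901932. DKO-only regions made up 57.4% of the regions on Y and 14.3% elsewhere (Fisher's exact test, adjusted p = 8.7e-15). This was the 1 comparison of 42 that passed an adjusted p of 0.05. On X, 125 of 799 regions (15.6%) were DKO-only, which did not pass (Fisher's exact test, adjusted p = 0.72). A stretch of 1300 kb on X, 120100001 to 121400000, held 65 regions, none called in a WT library. Of these, 56 were called in DKO replicate 1 and 41 in DKO replicate 2, and 32 were DKO-only. Outside this stretch, 93 of 734 regions on X (12.7%) were DKO-only, against 14.2% on the autosomes. The stretch was chosen after its values were seen. Without X, Y and the mitochondrial sequence, 5429 DKO-only and 240 WT-only regions remained over the full lists, and 1000 and 831 at equal length. The genotypes therefore differed in calls on Y in every library, beside each autosomal count given here.

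**Figure D3:**
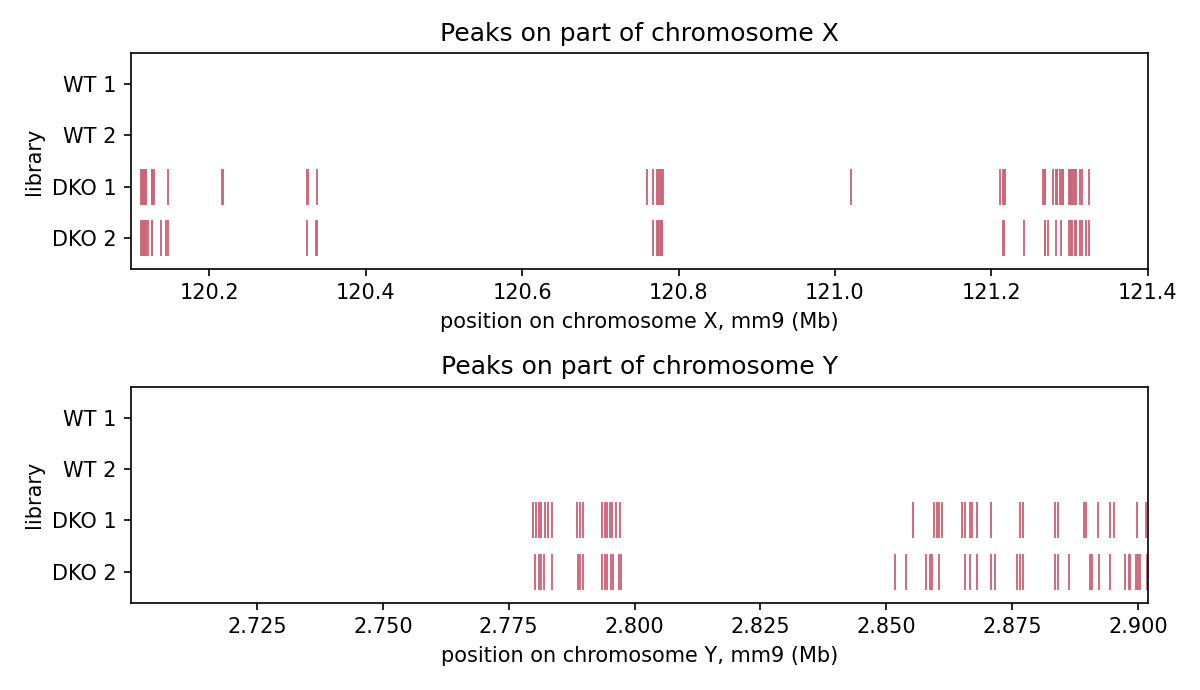
Positions of the deposited peaks on X (top, 120100001 to 121400000) and on Y (bottom, 2700001 to 2901932) in mm9, in Mb, with 1 row per library and 1 line per peak, red for DKO. The WT rows are empty in both stretches.

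Over the full lists, DKO-only regions lay together along the chromosomes more than the union regions at large. There were 360 windows of 100 kb with at least 3 DKO-only regions, against a mean of 278 (central shuffles from 252 to 305). The permutation p of 0.0001 was the smallest that 10000 shuffles can give. On the autosomes alone the values were 353 and 269. Neighbouring peaks of 1 broad site that do not overlap count as separate regions here. Merging peaks within 500 bp left 5097 DKO-only regions. The window counts of either class were not repeated on regions merged in that way. The richest windows were on Y, 2700001 to 2800000 with 14 DKO-only regions and 2800001 to 2900000 with 12. They were followed by X 120100001 to 120200000 with 9, and by X 121300001 to 121400000 with 8. The first autosomal window, on chromosome 5 from 114200001 to 114300000, held 8 DKO-only regions. DKO replicates 1 and 2 had calls in 12 and 11 of its 13 regions, and WT replicates 1 and 2 in 4 and 0. At equal list lengths 11 windows were found on all chromosomes, against a mean of 4.34 (permutation p = 0.0038). Without X, Y and the mitochondrial sequence these fell to 5, against a mean of 3.61 (permutation p = 0.29), so no excess was found on the autosomes at this length. With DKO replicate 2 left out, no excess was found, at 2507 windows against a mean of 2521 (permutation p = 0.73). The class then held 17922 regions, 12329 of them called in DKO replicate 1 alone. Because most of its regions were new to the class, this cannot tell whether the excess depends on DKO replicate 2. Without DKO replicate 1 the window count was 540 against a mean of 499 (permutation p = 0.0061). Without WT replicate 1 it was 1094 against 970, and without WT replicate 2 it was 478 against 389 (permutation p = 0.0001 each).

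WT-only regions formed 2 such windows, against a shuffled mean of 0.0501 (permutation p = 0.0013). On the autosomes alone there was 1, against 0.0463 (permutation p = 0.046). At equal list lengths there were 7 against 2.41 (permutation p = 0.011), and 6 against 2.14 on the autosomes (permutation p = 0.019). Of the 847 WT-only regions at that length, 736 had a DKO peak in the full lists. Most of that class was therefore not WT-only over the full lists. Of the 2 windows over the full lists, the first lay on chromosome 3, 127500001 to 127600000, with 3 WT-only regions of 10. The other lay on X, 4600001 to 4700000, with 3 of 8. The next 6 windows were tied at 2 WT-only regions each. They lay on chromosome 1 at 85100001 to 85200000, chromosome 15 at 85000001 to 85100000, chromosome 18 at 32700001 to 32800000, chromosome 3 at 10200001 to 10300000, chromosome 5 at 74200001 to 74300000 and chromosome 7 at 134700001 to 134800000. In the chromosome 15 and chromosome 5 windows these were the only regions, and neither DKO library had a call there. Without DKO replicate 1 there were 2 windows among 812 WT-only regions, against a shuffled mean of 1.67 (permutation p = 0.50). Leaving out WT replicate 1 or WT replicate 2 gave 7 or 27 windows, against means of 1.76 and 18.5 (permutation p = 0.0018 and 0.028). Without DKO replicate 2 there were 3, against 0.084 (permutation p = 0.0001).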

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

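The tests in this part were chosen after the peak lists had been seen. Peaks on chromosome Y appeared in both DKO libraries, 55 in replicate 1 and 57 in replicate 2, and in neither WT library. They are a signal outside the comparison by genotype that the labels describe, and the labels give no sex. A candidate explanation is that the DKO cells came from males and the WT cells from females. The Y peaks raised it and so do not test it. Cells with a single X should also have less background on X, and this was written down before the background on X was looked at. The median local background at X peaks was 0.79 and 0.80 of that at autosomal peaks in WT replicates 1 and 2, and 0.68 and 0.70 in DKO replicates 1 and 2. The mean DKO ratio was 0.87 of the mean WT ratio. Because the DKO lists are longer, the ratio was taken again at sites called in all 4 libraries. It was 0.76 and 0.78 for WT and 0.67 and 0.63 for DKO, with DKO at 0.84 of WT. Both ratios came out as written down for a sex difference. They separate 2 libraries from 2, for which the smallest exact permutation p is 0.33. The share of X peaks at the lowest background was a second measure, here not scaled to the share of autosomal peaks. Unscaled, it separated the genotypes over the full lists but not at the sites called in all 4 libraries. Over the full lists it was 29.6 and 34.6% for WT and 50.9 and 68.8% for DKO, against 8.09, 7.58, 16.1 and 9.75% of autosomal peaks. At the shared sites it was 17.4 and 27.2% for WT and 18.3 and 64.0% for DKO, against 2.92, 3.84, 1.69 and 3.63% of autosomal peaks in the same order. The background cannot fall below that level. The median of the X peaks had reached it in both DKO libraries over the full lists and in DKO replicate 2 at the shared sites, so the size of the drop is not a measure of X copies. The use of a control library is not given. Without one the local background holds the reads of the site itself, and a difference in signal over background between the genotypes was not separated from sex. The X share of peaks was 1.70 and 1.68% in WT and 1.98 and 1.65% in DKO. Why the X stretch of 1300 kb had 0 WT calls was not tested, and reads from Y placed on X stay open. Reads of repeats from other chromosomes placed on Y stay open. The background on X had been written down as a test of them too, with the lowest WT ratio, 0.79, as the bound. That was wrong, since repeats placed on Y predict nothing for X. Whether sex also accounts for some of the 5429 DKO-only regions outside X, Y and M cannot be told apart from the loss of Tcf1 and Lef1, because every DKO library and no WT library has Y peaks.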

How the results depend on the processing

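The settings without X, Y and M, the fold minimum of 8 and the leave-one-out values for peak number, overlap and clusters were added after seeing the data. DKO-only regions kept within 1.5 times of 5593 in 8 of 14 settings and WT-only regions within 1.5 times of 246 in 5 of 14. Both tallies include the replicate number as a block, a setting that cannot change the counts. The settings that did not keep within this bound were as follows. At −log10 q of at least 5 and 10, WT-only regions fell to 139 and 49, and at 10 the log2 difference in peak number rose to 1.50. At equal list lengths there were 847 WT-only and 1057 DKO-only regions, and at 5536 peaks per list 386 and 498. Counting a call in at least 1 library of the genotype and none of the other gave 2494 and 19598. A fold of at least 8 in both libraries left 7 and 927, but folds ran higher in the DKO lists, so this bar is not equal for the genotypes. Windows of 50 kb gave 1 WT-only and 191 DKO-only clusters, equal list lengths 7 and 11, equal list lengths without X, Y and M 6 and 5, and removal of X, Y and M left 1 WT-only cluster. Fewer peaks, smaller windows or fewer regions are the construction of these settings. Leaving out 1 library gave 287 to 1913 WT-only and 6490 to 17922 DKO-only regions over the full lists, and 1302 to 3253 and 1689 to 2342 at equal lengths. It gave 2 to 27 WT-only and 478 to 2507 DKO-only clusters, and log2 differences in peak number of 0.62 to 1.32. The excess of the Jaccard index within genotypes over that between them, 0.0728, ranged from -0.000173 without DKO replicate 1 to 0.154 without WT replicate 1. A class then rests on 1 library of a genotype, or on 1 fewer to be absent from. The labels give no pairing beyond shared replicate numbers. With the replicate number as a block the classes are by construction the same, 246 and 5593 regions, and the log2 difference stays 0.97 (exact sign test over 2 pairs, p = 0.5, the smallest possible). Within-genotype differences of same-numbered libraries correlated at 0.03 at equal lengths and −0.07 over the full lists. The 20 named regions stayed in their class in the 4 settings tried for them. They were chosen for high folds and most of these settings only remove weaker peaks, so this was largely fixed by the choice. Tests needing an mm9 genome or annotation were not run. The listing thresholds limit what absence of a call can show.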

Other observations

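The 5 regions with the highest folds in WT replicate 1 were called in all 4 libraries. On chromosome 12, 3109868 to 3110114 had folds of 86.0 and 87.1 in WT replicates 1 and 2 and 87.8 and 85.1 in DKO replicates 1 and 2. On chromosome 6, 103599106 to 103599286 had 90.9, 87.5, 101.1 and 98.0 in the same order. On chromosome 9, 35112802 to 35113171 had 57.6, 58.4, 56.2 and 52.4. The other two lay on X and chromosome 2. X 139917547 to 139917654 had 81.7, 80.4, 100.1 and 95.6, and chromosome 2, 5300278 to 5300423, had 47.3, 39.5, 56.5 and 59.1. Folds ran higher in the DKO lists in general, so they are not compared between genotypes. The second-largest group called in 3 or more libraries was the 4504 regions present in WT replicate 1 and both DKO libraries and missing from WT replicate 2. The mirror group, missing from WT replicate 1, held 897.

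The counts at equal list lengths were planned. The explanations of list length and of genotype-only regions, and what each predicts, were written down after the data had been seen. The DKO lists were longer and DKO-only regions outnumbered WT-only regions. Greater read depth of the DKO libraries is argued against, since the mean background of the DKO libraries was 0.80 of that of the WT libraries and both DKO values lay below both WT values. The background also grows with the fragment length. Divided by the width of the narrowest peak, taken as a sign of that length, the ratio was 0.89, with 16.1 and 15.1 for WT and 14.5 and 13.3 for DKO (fragments per position per 1000 bp). Part of the gap is then not depth, but the DKO values stayed below the WT values. This argument assumes that no control library set the background, and the use of one is not given. Higher signal over background in the DKO libraries stays open. The ratio of DKO-only to WT-only regions fell to 1.25 at equal list lengths, but equal lengths tie the counts together, so this cannot be told apart from a wider gain of accessible sites.

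The regions classed as genotype-only at equal list lengths numbered 1.94 times those of the highest other split of the libraries. In the full lists, 736 of the 847 WT-only and 239 of the 1057 DKO-only regions had a peak of the other genotype. One gain in signal common to all sites of a genotype stays open as the source of the regions classed at equal length. The lists were cut at different −log10 p to reach equal length, 27.3 and 13.6 in DKO replicates 1 and 2 and 10.8 and 5.4 in WT replicates 1 and 2, and there are only 3 splits. A difference in digestion or library preparation that favours some sites, a possible sex difference and the loss of Tcf1 and Lef1 all run along the same split and were not tested apart. The narrowest peaks, 93 and 97 bp in WT against 85 and 86 bp in DKO, show that the libraries differ along it in a technical measure as well.

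One hypothesis was written down before its result was seen, that DKO-only regions lie nearer to sites called in all 4 libraries than WT-only regions do. On the autosomes the median distance was 35.8 kb for 5429 DKO-only and 52.0 kb for 240 WT-only regions, a difference of -16.2 kb (two-sided permutation p = 0.0005, 10000 permutations of regions). At equal list lengths it was -8.04 kb, 57.4 against 65.5 kb (permutation p = 0.081), which does not pass. The first result may therefore come from the unequal lists.

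Neighbouring regions were also compared across other pairs of libraries on the autosomes, over the full lists. Windows with at least 3 regions were 1.31 times the shuffled mean for DKO-only regions. They were 0.96 times for the 2016 regions called in both replicates 1 and neither replicate 2 (permutation p = 0.62), and 1.01 times for the 12012 regions of DKO replicate 1 alone (permutation p = 0.36). For the 4440 regions missing from WT replicate 2 alone the value was 1.18 (permutation p = 0.0039). Whether these excesses differ from each other was not tested.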
